A study of Danio rerio with 26 samples.

How the data were processed

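Gene expression was measured on 26 microarrays of tissue from the telencephalon of adult zebrafish of the gfap:GFP reporter line, in which green fluorescent protein is driven by the gfap promoter of radial glia. Tissue came from the dorsal parenchyma, the dorsal subventricular zone (SVZ) and a medial neurogenic zone, 2 or 7 days after a stab wound or without a lesion. The labels call each array a biological replicate and do not say how many animals each holds. The treatment text describes injection through a small hole in the skull, whereas the series design names a stab wound. The design text names the dorsal SVZ and dorsal parenchyma only, and the medial zone was grouped from the sample labels.

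The deposited values are log2 intensities that the authors made with RMA (background correction, quantile normalization and summary per probe set) in Affymetrix Expression Console 1.2, per the labels. The table held 75212 probe sets, had no missing values, and was not centred per gene. The array medians lay between 3.01 and 3.21 and the upper quartiles between 4.70 and 5.02 on the log2 scale. The scanner files were not available, so another background correction or a scan batch could not be tried, and precision was limited by the number of arrays, 2 to 4 per group. No genome build was stated, and no position is given.

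Probe sets were named from the platform annotation, and symbols were matched by Entrez identifier to a current list of zebrafish genes used for names only. Of the probe sets, 20806 carried exactly 1 symbol, 855 carried several and 53551 carried none. The Entrez identifier was found for 20323 of the first kind, and it changed 1 symbol. Each gene was taken as its probe set with the highest mean over all arrays, which gave 19260 genes, of which 1365 had more than 1 probe set. The cyp1a probe set carried several symbols and cyp1c1 and cyp1c2 were not among the named probe sets, so these target genes of the aryl hydrocarbon receptor (AhR) were not analysed.

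A model with 1 mean per group was fitted to all 26 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes). Tables and plots used python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. There were 15 comparisons: each time after lesion against no lesion, and day 7 against day 2, in each region, the unlesioned regions against each other, and the difference of the lesion effect between regions. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted over the 19260 genes of each comparison. Every adjusted p given for a gene comes from limma. Means are given with the SD and n, and log2 fold changes with the SE.

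There were 25 gene lists, of AhR components, AhR targets, tryptophan-kynurenine metabolism, microglia and macrophages, neutrophils and mast cells, lymphocytes, erythrocytes and thrombocytes, inflammatory mediators, complement, interferon response, lysosome, cell cycle, radial glia, Notch pathway, neurogenic progenitors, mature neurons, oligodendrocytes, endothelial and mural cells, extracellular matrix, ciliated ependyma and choroid plexus, pallial territory, subpallial territory, immediate early and stress genes, cholesterol synthesis, and glycolysis and hypoxia. Groups, comparisons, lists, the rule for named genes and the alternatives were fixed before the data were examined. Lists were tested against all other genes with camera at an inter-gene correlation of 0.01, and again with an estimated correlation, adjusted over the 25 lists and 15 comparisons together. Genes called within a list were also counted with p adjusted over the list alone.

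Named genes followed 3 parts of a rule. The first part took the 6 largest rises and 6 largest falls for lesion against no lesion, and 5 of each for the other comparisons, among called genes whose 2 groups did not overlap (not asked of differences between regions). Such a gene also needed a group mean above the median of the table, 3.09, and a symbol that was not a clone name, where the prefixes cb, fb, fc and fj counted as clone names when a digit followed. The second part took up to 4 members with the smallest adjusted p in each list discussed, and the third part took all members of both AhR lists together with gfap, pcna, mki67, lcp1 and il1b. The summary statements below draw on all of these.

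The alternatives were array quality weights, the estimated list correlation, removal of the third of genes with the lowest mean (12840 genes left), every probe set in place of 1 per gene, quantile normalization again, subtraction of the array median, the replicate number as a fixed or random block, a prior with trend and robust fitting, a fit to the groups of 1 region or comparison alone, and leaving out each array. The effect averaged over the 3 regions, and a fit without the 2 arrays of lowest quality weight (parenchyma day 2 replicate 1 and day 7 replicate 3), a random block of the day 7 arrays with the same number, and a split of the cholesterol list by level, were chosen after the data had been seen. So were 2 further lists, of 38 circadian clock genes and 16 glucocorticoid targets, tested with limma's fry in the mean effects at days 2 and 7 and their difference. The mixed p of these 6 tests was adjusted by Benjamini-Hochberg; fry does not compare a list with other genes. A score of each array, the first principal component of these genes within groups, was added to the model as a covariate. Medians of 2 lists were compared by two-sided permutation of their members (100000 draws). The model was tested on simulated data, in which it called between 34% and 60% of changes of 1 on the log2 scale, and between 94% and 99% of changes of 2, in the 6 comparisons of lesion with no lesion. The simulated noise was independent, with 1 variance per gene for all regions, and changes were placed in genes with a mean above the table median. Recovery may thus be lower in a region that varies more, or for genes of lower level.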

Results

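The data were log2 intensities of 19260 genes on 26 arrays in 9 groups. The dorsal parenchyma had 3 arrays at day 2, 3 at day 7 and 2 without a lesion. The dorsal SVZ, the ventricular layer that holds radial glia and neural progenitors, had 3 arrays in each group. The medial neurogenic zone had 4 arrays at day 2, 3 at day 7 and 2 without a lesion. The arrays separated first by region, on a first principal component with 31.1% and a second with 19.4% of the variance of the 13921 genes above the table median.

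**Figure D1:**
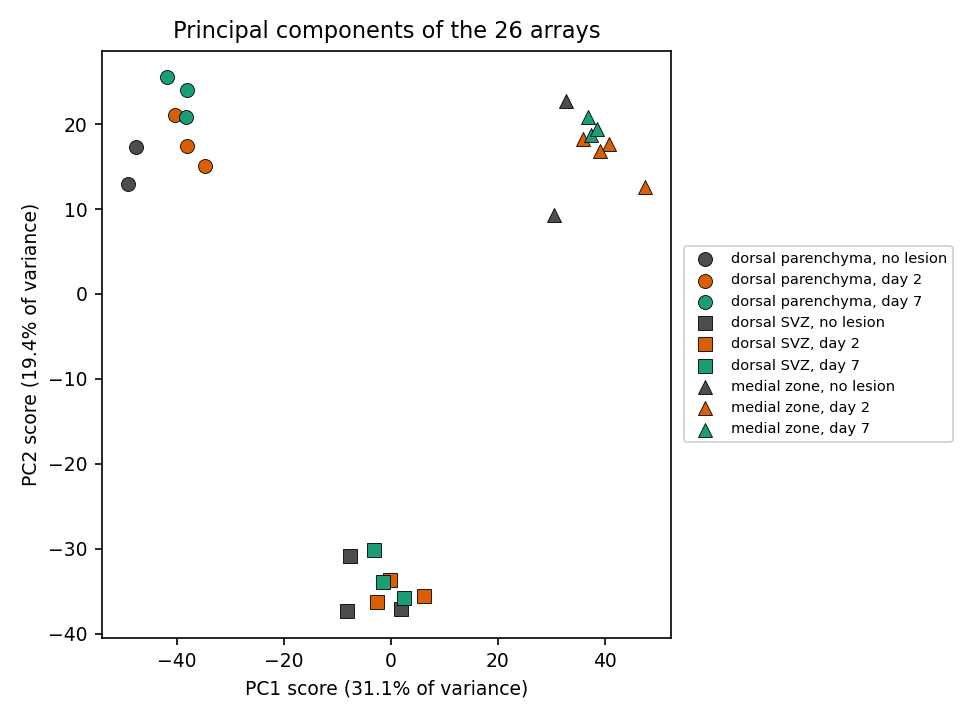
Scores of the 26 arrays on the first and second principal components (arbitrary units; each point is 1 array, shape gives the region and colour the time after lesion). The 3 regions lie apart, and times within a region lie close together.

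The first question was what the stab wound changed in each region by day 2. In the dorsal parenchyma the largest rises were in genes of microglia and macrophages, the resident and invading phagocytes of the brain. The list of their markers had 21 of 28 members risen (23 adjusted over the list alone), none fallen and 7 not passed, with a median log2 fold change of 2.31 (camera adjusted p = 1.0e-43). The macrophage pore protein gene mpeg1.1 was at 8.61 ± 0.60 (SD, n = 3) at day 2 and 4.47 ± 0.10 (SD, n = 2) without a lesion, a 17.6-fold rise (adjusted p = 1.6e-07). The lipid carrier apoeb rose 12.6-fold, the phagocytic receptor havcr1 10.3-fold and the amino acid transporter slc7a7 8.30-fold. Further large rises were seen on and off that list: the C1q-like gene c1ql1 rose 27.2-fold, the galectin lgals9l1 (on the list) 23.3-fold, the lysosomal membrane gene laptm5 (on the list) 22.4-fold, the tetraspanin tspan36 16.1-fold and the chemokine receptor ccr12a 15.6-fold. The unlesioned means of c1ql1 (2.80) and tspan36 (2.99) lay under the table median of 3.09, a level not shown to be above background, so these folds are not exact and their order is open. The same holds for ctsk, atf3 and the fall of kcnk2a below.

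Lysosomal genes rose with them, 9 of 20 over all genes and 11 not passed (13 risen and 1 fallen adjusted over the list alone, median 0.88, camera adjusted p = 4.4e-13). Among them, the proteases ctsk and lgmn rose 10.9-fold and 2.99-fold, and psap, which encodes a precursor of sphingolipid activators, rose 3.25-fold. Members of other immune lists also rose: the granulocyte receptor csf3r by 3.85-fold (2 of its list risen, and 2 risen and 1 fallen adjusted over the list alone), and the shared interleukin receptor chain il2rga by 4.14-fold as 1 of 15 lymphocyte genes (1 risen and 1 fallen adjusted over the list alone). The adhesion gene pecam1a, on the endothelial list, rose 5.09-fold as 1 of 28 members of that list (3 adjusted over the list alone). On the list of inflammatory mediators 3 of 35 members rose (3 adjusted over the list alone), among them the transcription factor stat3 (2.55-fold) and the leukotriene hydrolase lta4h (2.70-fold). That list test was lost with an estimated correlation (adjusted p = 0.189). The third, nfkbiaa, had probe sets that moved in opposite directions. The cytokine gene il1b was not called (log2 fold change -0.45, SE 0.29, adjusted p = 0.568).

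Stress genes also rose in the parenchyma: 4 of 32 were higher and 1 lower (6 and 2 adjusted over the list alone, median 0.49). The injury-induced factor atf3 was up 3.52-fold, jun 2.74-fold and the thioredoxin inhibitor txnipa 4.71-fold. The list test was lost with an estimated correlation (adjusted p = 0.476). Of 34 cell cycle genes 2 rose (4 adjusted over the list alone, median 0.39), the spindle gene nusap1 by 3.43-fold and the topoisomerase top2a by 2.05-fold. That list test was also lost with an estimated correlation (adjusted p = 0.324). The proliferation marker MKI67 was not called (log2 fold change 1.25, SE 0.35, adjusted p = 0.0682). The neuronal tubulin gene tubb5 and the progenitor factor sox11a rose 2.84-fold and 3.12-fold, as 2 of 32 genes of neurogenic progenitors and immature neurons (2 adjusted over the list alone). The glycolytic enzyme aldoab rose 3.28-fold. No radial glia gene passed the test, and the intermediate filament gene gfap had a log2 fold change of 0.74 (SE 0.39, adjusted p = 0.459).

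In all, 392 genes were called in the parenchyma at day 2, 328 higher and 64 lower. The lower count was 148 after subtraction of the array median and 127 after quantile normalization again. The largest falls were in the potassium channel gene kcnk2a (3.53-fold), hsd20b2 (3.39-fold), pnp5a (3.29-fold), glipr1b (3.00-fold), the lipid transporter mfsd2aa (2.90-fold) and erich3 (2.74-fold). Each of these 6 calls ended when 1 or more of the arrays of the comparison was left out. Cholesterol synthesis had 1 of 22 members lower (2 adjusted over the list alone, median -0.33, and -0.118 without unlesioned replicate 1), the feedback regulator insig1 (2.55-fold). The second probe set of insig1 hardly moved (log2 fold change -0.05). The list test was lost with an estimated correlation (adjusted p = 0.448). The count fell to 241 without day 2 replicate 3 and 231 without unlesioned replicate 1, to 247 with array weights and to 80 in a fit of the parenchyma alone. Among the list members above, that fit ended the calls of nfkbiaa, psap, nusap1, top2a, stat3, lta4h, txnipa, sox11a, aldoab and insig1. The parenchyma arrays varied most, with a median residual SD of 0.326 for genes above the table median (0.255 in dorsal SVZ, 0.285 in medial zone). The main model did not allow for this, as it used a single variance per gene for all regions. The calls of stat3, txnipa, jun, lta4h, sox11a, top2a and insig1 also ended without 1 of the unlesioned replicates, and that of nfkbiaa without 4 of the 5 arrays. Those of top2a and insig1 ended without day 2 replicate 3 and, for insig1, replicate 2.

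In the dorsal SVZ at day 2 the same cell type list rose and cholesterol synthesis genes fell. Of the microglia and macrophage markers 9 of 28 rose and 19 were not passed (20 risen adjusted over the list alone, median 1.09, camera adjusted p = 4.8e-28). The gene mpeg1.1 was at 6.96 ± 0.29 (SD, n = 3) against 4.55 ± 0.23 (SD, n = 3) without a lesion, a 5.32-fold rise. The secreted galectin-binding gene lgals3bp.1 rose 6.16-fold, lgals9l1 6.22-fold, c1ql1 5.38-fold, ccr12a 5.34-fold, apoeb 3.97-fold and the lysosomal protease ctsc 4.44-fold. Of 22 cholesterol synthesis genes 9 fell, 13 were not passed and none rose (17 fallen adjusted over the list alone), with a median log2 fold change of -0.79 (camera adjusted p = 5.5e-38). All 22 had a negative sign. The fallen members held enzymes along the pathway: squalene epoxidase sqlea fell 6.16-fold, hydroxymethylglutaryl-CoA synthase hmgcs1 6.04-fold, lanosterol demethylase cyp51 4.25-fold and sterol desaturase sc5d 3.66-fold. The retinoid isomerase gene rpe65a and the transferrin receptor gene tfr1b fell 4.44-fold and 4.34-fold.

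The cell cycle list was higher in the dorsal SVZ at day 2 with a median of 0.52 (0.329 without day 2 replicate 3) and 32 of 34 members positive, although only top2a was called over all genes (2.06-fold) and 12 members rose adjusted over the list alone. Lysosomal genes had 2 of 20 risen (6 adjusted over the list alone, median 0.35), and the estimated correlation kept the cell cycle and lysosome lists (adjusted p = 0.0420 and 0.0442). The interferon list held 1 risen member of 27, the transcription factor irf9 (2.15-fold, 1 adjusted over the list alone), and was lost with an estimated correlation (adjusted p = 0.115). The endothelial list had pecam1a risen 2.50-fold (1 risen and 1 fallen adjusted over the list alone), and the matrix cross-linker loxl2b fell 3.2-fold as 1 of 38 matrix genes (4 risen and 1 fallen adjusted over the list alone). The lists of erythrocytes, complement, mature neurons and glycolysis passed camera with medians of 0.23, 0.11, -0.10 and -0.10 and were lost with an estimated correlation (adjusted p = 0.299, 0.189, 0.627 and 0.448). Without 1 array the median of erythrocytes ran from 0.0785 to 0.371 and that of mature neurons from -0.1745 to -0.0282. Those of complement and glycolysis reached 0.0695 and -0.057. No radial glia, Notch or neurogenic progenitor gene was called, and 1 progenitor gene rose and 1 fell adjusted over the list alone.

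The dorsal SVZ call covered 52 genes, 35 higher and 17 lower. The count fell to 14 without day 2 replicate 3, 30 without day 2 replicate 1, and 23 and 16 without unlesioned replicates 2 and 3. It was 31 over every probe set and rose to 85 with array weights. With a clock and glucocorticoid score of each array in the model, a covariate chosen after the data had been seen, it was 33 (30 shared). Of the genes named for this comparison, mpeg1.1, lgals3bp.1, sqlea, hmgcs1, cyp51 and sc5d stayed called without any 1 array. Of the rest, apoeb was lost only without day 2 replicate 3, and the others were lost without 2 or more of the 6 arrays.

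In the medial zone at day 2 cell cycle genes rose along with the phagocyte markers. Of 34 cell cycle genes 6 rose and 28 were not passed (23 risen adjusted over the list alone), with a median of 0.93 (camera adjusted p = 4.2e-29). MKI67 rose 3.43-fold, from 5.32 ± 0.36 (SD, n = 2) to 7.09 ± 0.34 (SD, n = 4), the kinetochore gene CENPF 3.05-fold, top2a 2.50-fold and the spindle motor kif11 2.33-fold. The replication clamp pcna was not called (log2 fold change 0.89, SE 0.26, adjusted p = 0.161). Of the microglia and macrophage markers 11 of 28 rose (22 adjusted over the list alone, median 1.2, camera adjusted p = 3.7e-29), with mpeg1.1 up 4.18-fold and apoeb 4.36-fold. Large rises were in c1ql1 (12-fold), lgals9l1 (7.21-fold), the proteasome activator psme1 (6.51-fold), the actin nucleation gene arpc1b (5.95-fold), the Fc receptor chain fcer1g (5.55-fold) and ccr12a (5.29-fold). The complement gene c4 rose 5.06-fold as 1 of 18 complement members (2 adjusted over the list alone). The unlesioned means of c1ql1, c4 and ctsk lay under the table median, so their folds here are not exact.

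Cholesterol synthesis had 5 of 22 members fallen in the medial zone (12 adjusted over the list alone, median -0.69, camera adjusted p = 2.3e-15). They included sqlea (4.84-fold), insig1 (3.2-fold), the rate-limiting reductase hmgcra (3.08-fold), cyp51 (2.99-fold) and msmo1 (2.64-fold). The second probe set of insig1 had a log2 fold change of -0.19 here. The growth factor receptor inhibitor errfi1a also fell, by 3.26-fold. The interferon list had 1 of 27 risen, irf9 at 2.48-fold (5 adjusted over the list alone, median 0.31). It held with an estimated correlation (adjusted p = 0.00923), as did microglia, cell cycle and cholesterol (adjusted p = 0.00908, 0.00404 and 0.00605). Single risen members of further lists were stat3 (2.47-fold), ctsk (3.15-fold), pecam1a (2.89-fold), the cilium gene enkur (2.12-fold), the subpallial factor gsx1 (2.36-fold), and the stress factors atf3 (3.11-fold) and ddit3 (2.38-fold). Adjusted over the list alone, the lists of these genes had 2 inflammatory, 2 lysosomal, 1 endothelial, 2 cilia and 1 subpallial members risen, and 3 stress genes risen and 2 fallen. The lists of neutrophils (median 0.33), inflammatory mediators (0.10), lysosome (0.17), cilia (0.27), mature neurons (-0.35) and pallial territory (-0.42) passed camera and were lost with an estimated correlation (adjusted p = 0.0834, 0.162, 0.421, 0.160, 0.144 and 0.193). Without 1 array the median of mature neurons ran from -0.555 to -0.1135 and that of inflammatory mediators from 0.036 to 0.184. Those of cilia and pallial territory reached 0.124 and -0.217.

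The medial call covered 95 genes, 73 higher and 22 lower. It fell to 61 without day 2 replicate 1, 44 without unlesioned replicate 1 and 24 without unlesioned replicate 2. It was 54 in a fit of the medial groups alone, 42 over every probe set and 51 with the replicate number as a block. With the clock and glucocorticoid score in the model it was 41 (38 shared). Of the genes named for this comparison c1ql1, arpc1b, c4 and cyp51 stayed called without any 1 array, and the others were lost without 1 or both of the unlesioned replicates, several of them also without a day 2 replicate.

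Across regions, 22 genes were higher and 1, insig1, was lower at day 2 in all 3 comparisons. In parenchyma and medial zone the fall of insig1 rests on 1 of its 2 probe sets. The shared risen genes held apoeb, c1ql1, ccr12a, ctsk, havcr1, laptm5, lcp1, lgals9l1, mpeg1.1, pecam1a and top2a. Parenchyma and dorsal SVZ shared 29 risen genes, where 0.596 were expected from independent calls. Dorsal SVZ and medial zone shared 23 risen and 5 fallen genes, where 0.133 and 0.0194 were expected. The test of the difference itself called 10 genes whose day 2 effect was lower in the dorsal SVZ than in the parenchyma, among them atf3 (log2 difference -2.24, not exact as its parenchyma mean without a lesion lay under the table median), tubb5 (-1.97) and cyp51 (-1.76). It called none between medial zone and dorsal SVZ (606 at an unadjusted p under 0.05, limma), where 19% of simulated differences of 1 were found. The 606 lie under a share of 0.05 of the 19260 genes, which is expected without any difference. The count of 10 fell to 0 without parenchyma day 2 replicate 3 and rose to 29 without replicate 1 or without parenchyma unlesioned replicate 2. It was 2 without parenchyma unlesioned replicate 1, dorsal SVZ day 2 replicate 1 or 2 or dorsal SVZ unlesioned replicate 2, and 5 without dorsal SVZ unlesioned replicate 1.

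**Figure D2:**
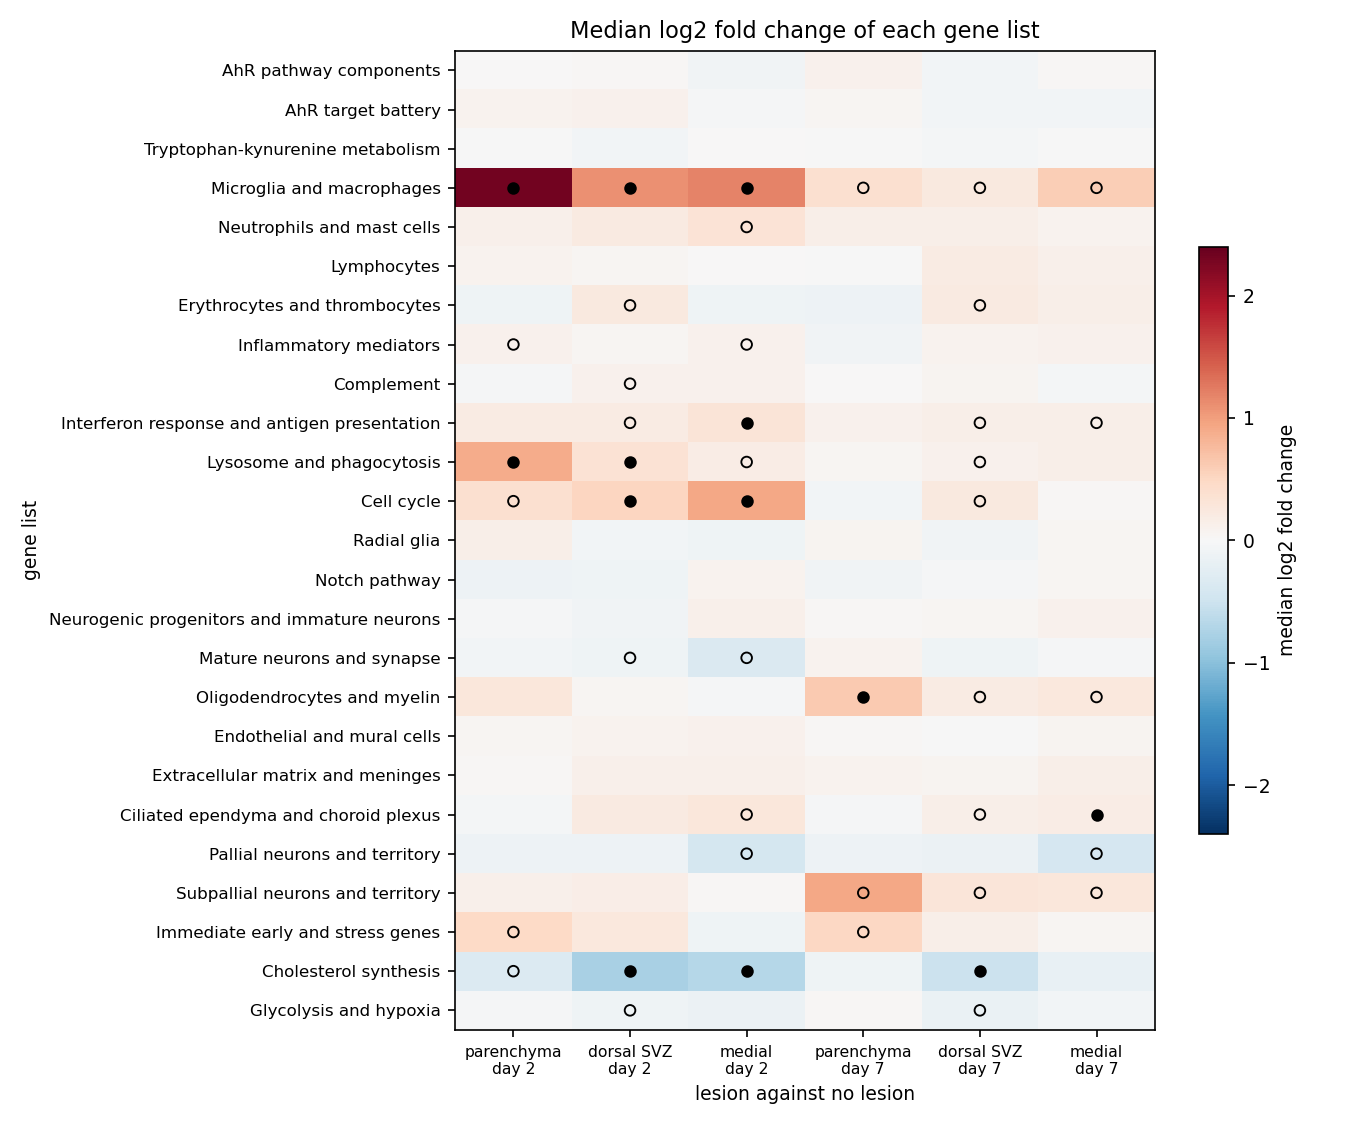
Median log2 fold change of each gene list (colour scale) in the 6 comparisons of lesion with no lesion. Circles mark camera calls, filled where the call held with an estimated correlation. The microglia median was 2.31 in parenchyma at day 2, and the cholesterol median was -0.79 in the dorsal SVZ.

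By day 7 few genes were called against unlesioned tissue. In the parenchyma 24 genes were called, 13 higher and 11 lower. There 2075 genes had an unadjusted p under 0.05 (limma), against 2417 at day 2. In simulated data with the same variance in all regions 45% of changes of 1 were found. The small count of calls thus does not show that few genes differed. The lists that stood out in the parenchyma were markers of subpallial territory and of myelin. The subpallial list had 1 of 23 members risen (15 adjusted over the list alone, median 0.92, camera adjusted p = 1.1e-08), the interneuron factor lhx6a at 3.46-fold. It was lost with an estimated correlation (adjusted p = 0.0856). All 15 measured oligodendrocyte genes had a positive sign (none called over all genes, 5 risen adjusted over the list alone, median 0.63). That list held with an estimated correlation (adjusted p = 0.00364), with a median of 0.399 without unlesioned replicate 1. In the same pieces, 419 genes outside the lists that were higher in unlesioned medial than dorsal SVZ tissue had a median of 0.26. The microglia list had no called member (8 risen adjusted over the list alone, median 0.38) and the stress list none (2 risen and 1 fallen adjusted over the list alone, median 0.50), and both were lost with an estimated correlation (adjusted p = 0.335 and 0.664).

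The largest rises in the parenchyma at day 7 were in the exchange factor gene iqsec1b (4.33-fold), lhx6a, the cohesin gene smc1a (3.42-fold), the G protein gene gna13b (3.37-fold), the chaperone dnaja1 (2.94-fold) and marcksa (2.61-fold). The tubulin gene tubb5 rose 2.48-fold as 1 of 32 genes of its list (3 adjusted over the list alone). The largest falls were in foxp1a (3.2-fold), the phospholipase pla2g4aa (2.90-fold), oxsm (2.65-fold), sprn (2.53-fold), vezf1b (2.52-fold) and krt97 (2.43-fold, to a mean under the table median). Of the 24 genes, 9 of the higher and 6 of the lower were also called at day 2. Both comparisons share the same unlesioned arrays, so the calls are not independent. In simulated data without change no called gene was shared, and independent lists of these sizes would share 0.221 and 0.0366. Neither value holds both the shared arrays and the effects, so the excess over them is not called a shared effect, and part of it can come from the shared arrays. The covariance of the 2 effects across genes was 0.0962, against 0.0475 in the simulated data. Their correlation was 0.609, against 0.601 in the simulated data, so that measure showed almost no excess. Each of these named calls was lost without at least 1 of the 5 arrays. The count rose to 98 without unlesioned replicate 2 and 43 without day 7 replicate 1, and to 38 with quantile normalization again. It fell to 11 with the replicate number as a block, 2 in a fit of the parenchyma alone and 1 with array weights.

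No gene was called at day 7 in the dorsal SVZ or the medial zone by limma (858 and 784 at an unadjusted p under 0.05). Without any change a share of 0.05 of the 19260 genes would have such a p, and both counts lie under that. In the dorsal SVZ the cholesterol list was still lower (median -0.52, 9 of 22 fallen adjusted over the list alone) and held with an estimated correlation (adjusted p = 0.00586). Further lists passed camera there with no called member: microglia (median 0.23), erythrocytes (0.21), interferon (0.15), lysosome (0.11), cell cycle (0.24), oligodendrocytes (0.19), cilia (0.14), subpallial (0.30) and glycolysis (-0.16). Each was lost with an estimated correlation (adjusted p = 0.448, 0.357, 0.122, 0.516, 0.476, 0.0843, 0.197, 0.480 and 0.438). In the medial zone the cilia list (median 0.18, from 0.114 to 0.346 without 1 array) held with an estimated correlation (adjusted p = 0.0442) and ended without unlesioned replicate 1. In contrast, microglia (0.59, 4 risen adjusted over the list alone), interferon (0.13), oligodendrocytes (0.26), pallial (-0.39) and subpallial (0.26) were lost with it (adjusted p = 0.160, 0.155, 0.160, 0.0856 and 0.442). The median of that subpallial list turned to -0.0823 without unlesioned replicate 2. No gene was called for a difference of the day 7 effect between dorsal SVZ and parenchyma or between medial zone and dorsal SVZ (1370 and 563 at an unadjusted p under 0.05, limma), but without 1 array up to 24 and 6 were. These tests found 18% and 14% of simulated differences of 1 on the log2 scale, so differences of that size are not excluded. The 563 genes lie under a share of 0.05 of the 19260 genes, which is expected without any difference, and the 1370 above it.

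Day 7 was then compared with day 2 to follow the lesion response over time. In the parenchyma 221 genes differed, 23 higher and 198 lower at day 7. Microglia and macrophage markers had 18 of 28 members fallen (23 adjusted over the list alone, median -1.82), with ccr12a down 13.2-fold, c1ql1 12.1-fold, mpeg1.1 10.1-fold, slc7a7 6.29-fold and havcr1 5.36-fold. The thiol reductase ifi30a and the adaptor grap2b fell 8.49-fold and 7.06-fold. Lysosomal genes had 9 of 20 fallen (13 adjusted over the list alone, median -0.89), among them ctsc (6.71-fold) and ctsk (6.26-fold). Cell cycle genes had 3 of 34 fallen (9 adjusted over the list alone, median -0.46), with MKI67 down 3.50-fold to a mean under the table median. The microglia and lysosome lists held with an estimated correlation (adjusted p = 0.00382 and 0.00446), and the cell cycle list did not (adjusted p = 0.110). The dopamine synthesis gene th rose 4.53-fold, stxbp6l 3.9-fold, prom2 6.36-fold, lhx6a 2.91-fold and the myelin gene cldnk 2.42-fold. Of these only the call of th held without any 1 array, and the second probe set of prom2 had a log2 fold change of 0.46. Oligodendrocyte genes were higher as a list (median 0.43, 3 risen adjusted over the list alone, adjusted p = 0.00605 with an estimated correlation). The 419 genes outside the lists that were higher in unlesioned medial than dorsal SVZ tissue had a median of 0.17 in this comparison. The lists of subpallial territory (0.67, 10 risen and 1 fallen adjusted over the list alone), inflammatory mediators (-0.14) and mature neurons (0.12) were lost with it (adjusted p = 0.160, 0.0653 and 0.476). The count fell to 135 without day 2 replicate 3 and to 59 in a fit of the 2 groups alone.

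In the dorsal SVZ 10 genes differed between the times, 3 higher and 7 lower at day 7. The sterol genes insig1 and cyp51 rose 3.07-fold and 2.49-fold and the glycine receptor gene glrba 2.11-fold. The second probe set of insig1 had a log2 fold change of 0.29. The cholesterol list rose with 2 of 22 members (8 adjusted over the list alone, median 0.40, adjusted p = 0.00774 with an estimated correlation). The largest falls were in ccr12a (5.60-fold), mpeg1.1 (4.82-fold), the peptide gene ostn (3.83-fold), lgals3bp.1 (3.37-fold) and nckap1l (3.19-fold). The microglia list had 1 of 28 members fallen (13 adjusted over the list alone, median -0.68), lost with an estimated correlation (adjusted p = 0.0538). So were lysosome (-0.22), cell cycle (-0.31) and oligodendrocytes (0.25) (adjusted p = 0.160, 0.167 and 0.117). Only mpeg1.1 and ostn stayed called without any 1 array. The count was 4 to 6 without 1 array, 4 over every probe set or in a fit of the 2 groups alone and 5 with the replicate number as a block. It was 4 (4 shared) with the clock and glucocorticoid score in the model.

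In the medial zone 81 genes differed between the times, 22 higher and 59 lower at day 7. Cell cycle genes had 8 of 34 fallen (22 adjusted over the list alone, median -0.92, adjusted p = 0.00364 with an estimated correlation), with CENPF down 3.36-fold, the cyclin ccna2 3.18-fold, the proliferation factor mybl2b 3.06-fold and top2a 2.29-fold. Cholesterol synthesis had 5 of 22 risen (13 adjusted over the list alone, median 0.59, adjusted p = 0.00719 with an estimated correlation), with sqlea up 5.85-fold, cyp51 2.75-fold, insig1 2.69-fold and hmgcra 2.55-fold. The activin subunit inhbaa rose 4.37-fold, tespa1 2.99-fold and the Notch target her4.1, a marker of radial glia, 1.84-fold. In turn c1ql1 fell 6.48-fold, psme1 4.56-fold, mpeg1.1 2.63-fold, c4 2.33-fold and irf9 1.83-fold. The microglia list (median -0.71, 13 fallen adjusted over the list alone), neutrophils (-0.12), interferon (-0.21), mature neurons (0.36), oligodendrocytes (0.29) and subpallial territory (0.33) passed camera and were lost with an estimated correlation (adjusted p = 0.115, 0.117, 0.160, 0.132, 0.0633 and 0.552). The count was 35, 48 and 35 without day 2 replicates 1, 3 and 4, and 37, 13 and 21 without day 7 replicates 1, 2 and 3. It was 30 over every probe set, 11 in a fit of the 2 groups alone, 21 with the replicate number as a block and 124 with array weights. With the clock and glucocorticoid score in the model it was 15 (14 shared). The calls of sqlea, inhbaa, cyp51 and mybl2b stayed without any 1 array.

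**Figure D3:**
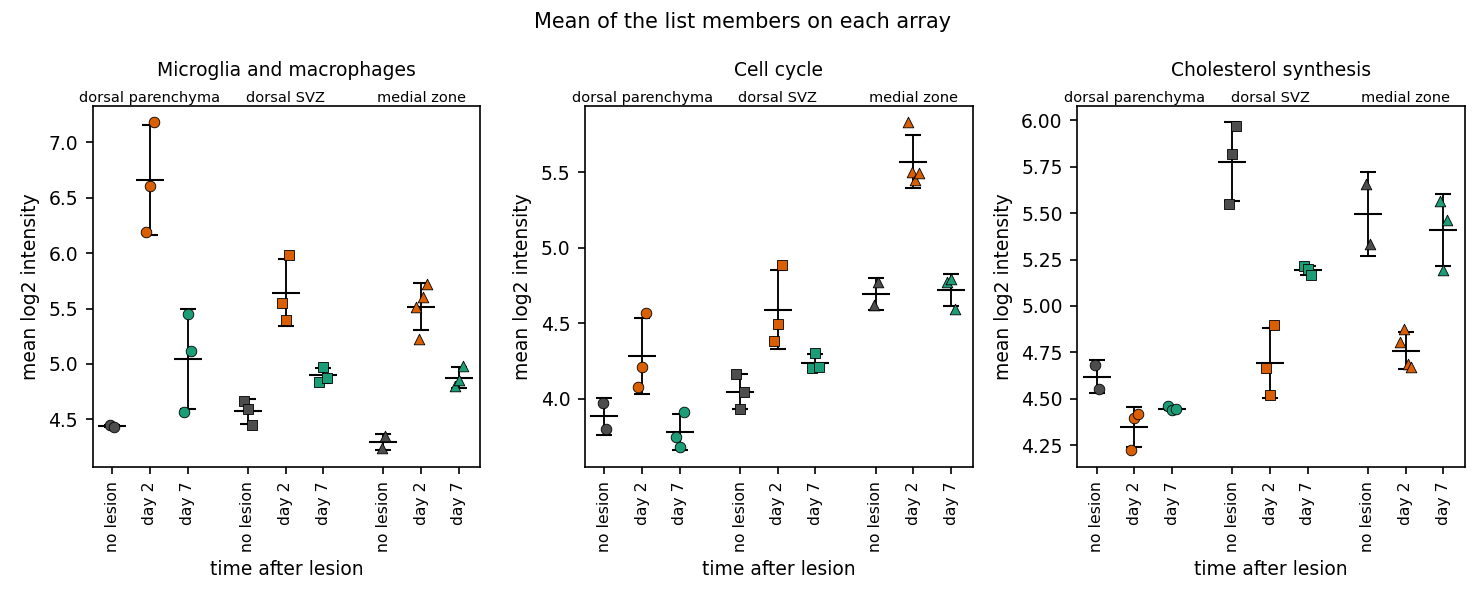
Mean log2 intensity of the members of 3 gene lists on each array, by region and time after lesion (points are arrays; the bar is the mean and the error bar the SD). Microglia and cell cycle means at day 2 lie above those of the unlesioned arrays of their region, and cholesterol means lie below them.

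The title of the series concerns the AhR pathway, a ligand-activated transcription factor with its partners and targets. None of the 11 measured AhR components and 12 targets was called by limma in any comparison of lesion with no lesion. Every group mean of ahr1a, ahrrb, foxq1a and gstp1.1 lay under the table median of 3.09, a level not shown to be above background. So did most group means of ahrra and foxq1b, those of nqo1 in parenchyma, and those of cyp1d1 in parenchyma and dorsal SVZ. For these genes a lack of change cannot be told from a lack of detection. The list tests gave camera adjusted p of 0.230 and 0.835 in parenchyma, 0.933 and 0.852 in dorsal SVZ and 0.823 and 0.463 in medial zone at day 2. At an unadjusted p under 0.05 there were 3, 1 and 2 components and 2, 1 and 3 targets in these regions at day 2, and 1, 0 and 1 components and 0 targets at day 7. At day 7 the camera adjusted p of the components and targets was 0.721 and 0.852 in parenchyma, 0.730 and 0.951 in dorsal SVZ and 0.881 and 0.326 in medial zone. The ADP-ribosyltransferase gene tiparp, a target that represses the receptor and a member of both lists, was the 1 member that fell adjusted over the list alone at day 2, in parenchyma and dorsal SVZ. Its log2 fold change at day 2 was -0.95 (SE 0.28, adjusted p = 0.0947) in parenchyma, -0.92 (SE 0.25, adjusted p = 0.215) in dorsal SVZ and -0.76 (SE 0.27, adjusted p = 0.339) in medial zone. At day 7 it was -0.43, -0.34 and -0.26 in the same order (adjusted p = 0.634, 0.9997 and 0.9996).

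Averaged over the 3 regions, a contrast added after the data had been seen, tiparp fell by 0.88 at day 2 (SE 0.155, adjusted p = 0.00118). That contrast takes arrays of different regions as independent. Each of the 10 day 2 arrays lay at or below 7.289, under the lowest unlesioned array at 7.56. The same arrays had low levels of klf9, a transcription factor that responds to glucocorticoids, at 4.434 to 6.933 against 7.381 to 8.685 without a lesion. Low tiparp was not limited to day 2. On day 7 replicate 1 it was at 7.173 in parenchyma, 7.175 in dorsal SVZ and 7.318 in medial zone, and on parenchyma day 7 replicate 3 at 7.158. The other day 7 arrays lay between 7.524 and 8.024. The receptor gene ahr2 had its largest changes in the medial zone, 0.71 (SE 0.25, adjusted p = 0.348) at day 2 and 0.81 (SE 0.27, adjusted p = 0.995) at day 7. The largest in the other regions was 0.23 (adjusted p = 0.971), in dorsal SVZ at day 2. The targets cyp1b1 and cyp1d1, which encode monooxygenases, had medial day 2 values of -0.70 (adjusted p = 0.506) and -0.80 (adjusted p = 0.337), and nqo1, which encodes a quinone reductase, -0.04 (adjusted p = 0.995). Genes of tryptophan-kynurenine metabolism, a source of receptor ligands, were not called either, the smallest adjusted p being 0.0867 for haao in dorsal SVZ at day 2 (1 member risen adjusted over the list alone).

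**Figure D4:**
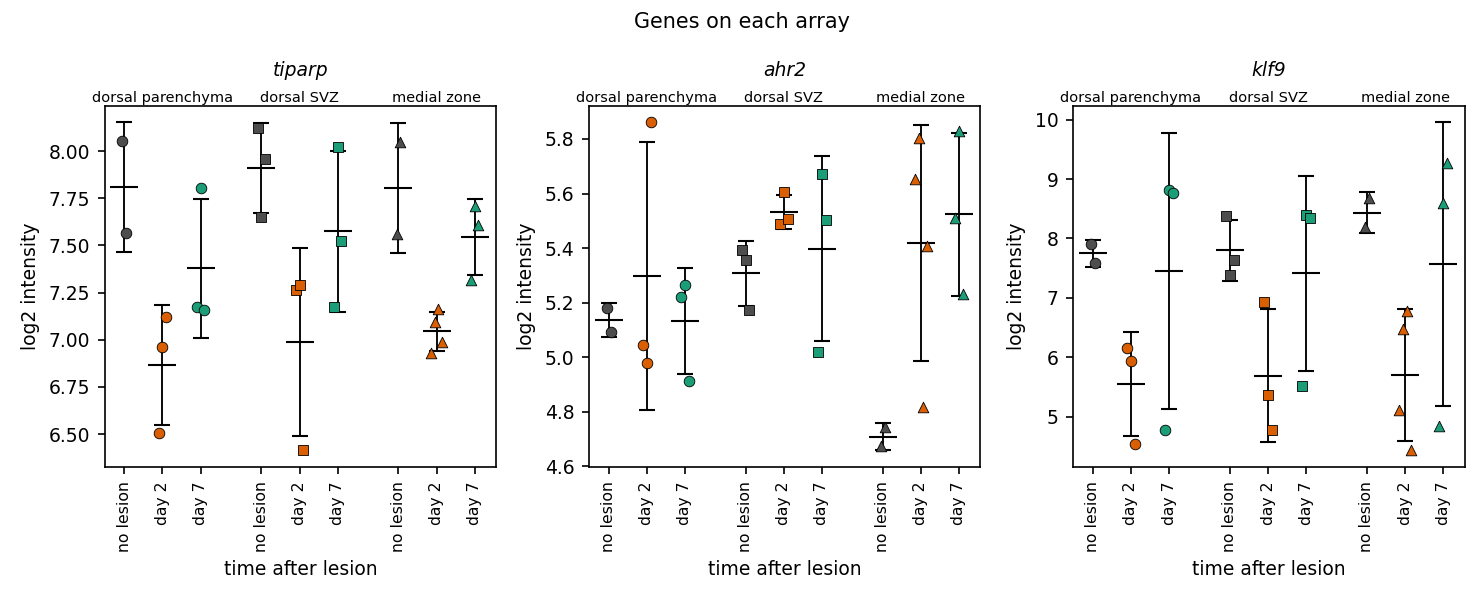
Log2 intensity of tiparp, ahr2 and klf9 on each array, by region and time after lesion (points are arrays; the bar is the mean and the error bar the SD). The day 2 arrays of tiparp lie at or below 7.289 and the unlesioned arrays at or above 7.56, and some day 7 arrays lie in the day 2 range. The level of klf9 is low at day 2 and on 1 day 7 array of each region.

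Unlesioned regions were compared to describe the tissues themselves. The dorsal SVZ differed from the parenchyma at 1289 genes, 941 higher and 348 lower. Radial glia genes were higher, 24 of 34 with 1 lower (26 and 1 adjusted over the list alone, median 1.75, adjusted p = 0.00269 with an estimated correlation), with mfge8a 24.9-fold, her4.1 24.6-fold, hepacama 23.4-fold and the Notch target her15.2 22.8-fold higher. Notch pathway genes had 11 of 30 higher (14 higher and 1 lower adjusted over the list alone, median 0.63, adjusted p = 0.00634 with an estimated correlation), among them notch3 (5.53-fold). Also higher were 9 of 22 cilia and choroid plexus genes (10 adjusted over the list alone, median 0.78, adjusted p = 0.00382 with an estimated correlation), and 13 of 22 cholesterol synthesis genes (15 adjusted over the list alone, median 0.94, adjusted p = 0.00872 with an estimated correlation). The largest differences were in the dipeptidase gene cndp1 (130-fold), the fatty acid binding gene fabp7b (118-fold), the sulfate transporter slc13a1 (85.9-fold), the gap junction gene gja1b (38.0-fold) and the retinol carrier rbp4 (35.9-fold). Of the AhR targets nqo1 and gstp1.2 were higher, 4.73-fold and 2.53-fold (2 of 12 adjusted over the list alone). The parenchyma means of rbp4, her4.1, her15.2 and nqo1 lay under the table median, so their folds are not exact. Parenchyma was higher in the myelin gene mbpa (27.2-fold), cart3 (8.91-fold), cbln2b (8.84-fold), pvalb6 (7.38-fold) and ndnfl (7.20-fold), and in the inhibitory neuron genes gad1b (3.69-fold) and slc32a1 (3.96-fold).

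The lists of neurogenic progenitors (median 0.37, 6 higher and 1 lower), mature neurons (-0.25, 1 and 6), endothelial cells (-0.73, 1 and 9) and subpallial territory (-0.39, 0 and 5) passed camera in that comparison and were lost with an estimated correlation (adjusted p = 0.144, 0.421, 0.189 and 0.420). Adjusted over the list alone they had 10 higher and 2 lower, 1 and 6, 3 and 12, and 0 and 8. Subtraction of the array median moved the median of all genes by -0.19 and gave 656 higher and 1075 lower. Quantile normalization again gave 698 and 504, so the excess of genes higher in dorsal SVZ turned with the first setting. The count was 798 without parenchyma unlesioned replicate 1, 803 without dorsal SVZ unlesioned replicate 1 and 2671 over every probe set, and the call of cart3 ended without parenchyma unlesioned replicate 2.

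The medial zone differed from the dorsal SVZ at 800 genes, 456 higher and 344 lower. Subpallial genes were higher, 20 of 23 (20 adjusted over the list alone, median 3.25, adjusted p = 0.000229 with an estimated correlation), with the interneuron factors dlx2a and dlx1a 41.0-fold and 26.4-fold higher. The somatostatin gene sst6.1 was 41.5-fold, rgs4 31-fold and six3a 26.6-fold higher, as were slc32a1 (18.7-fold), gad2 (10.1-fold), mbpa (20.0-fold) and the AhR target cyp1b1 (3.50-fold). The dorsal SVZ was higher in cndp1 (65.2-fold), slc13a1 (57.2-fold), fabp7b (53.6-fold), rpe65a (41.5-fold) and tmem72 (21.8-fold). The lower means of six3a and tmem72 lay under the table median, so these 2 folds are not exact. The dorsal SVZ was also higher in 5 of 22 cilia and choroid plexus genes (5 adjusted over the list alone, median -0.42, and -0.27 without medial unlesioned replicate 1, adjusted p = 0.00586 with an estimated correlation). Lists of cell cycle (0.62, 2 higher), neurogenic progenitors (0.14, 9 higher and 2 lower), pallial territory (-0.68, 1 and 4), matrix (-0.19, 3 lower), cholesterol synthesis (-0.16, 2 lower) and glycolysis (-0.18, 1 lower) were lost with an estimated correlation (adjusted p = 0.115, 0.115, 0.255, 0.117, 0.438 and 0.525). Adjusted over the list alone they had 5 higher, 15 higher and 6 lower, 2 and 8, 4 lower, 5 lower and 1 lower. Without 1 array the median of neurogenic progenitors ran from 0.0143 to 0.428 and that of cholesterol synthesis from -0.272 to -0.045. Those of matrix and glycolysis reached -0.335 and -0.112. Subtraction of the array median gave 375 higher and 436 lower, which turned the excess. Every probe set gave 1315, and the count was 531 without dorsal SVZ unlesioned replicate 2 and 419 and 524 without medial unlesioned replicates 1 and 2.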

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

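The tests of mean effects over the 3 regions, of the cholesterol and tiparp patterns (with the split of cholesterol genes by level), of single parenchyma arrays and of day 7 blocks were chosen after the results had been seen. The test of ventral tissue, the counts of other splits of the comparisons within a region and the tests of differences between regions were not.

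The fall of cholesterol synthesis genes at day 2 was weighed against a change of tissue content. If resident cells were only diluted by immune cells, radial glia genes would fall alike, but the cholesterol list lay below the radial glia list by a median of -0.52 in the mean day 2 effect (permutation p = 2.0e-05). The mature neuron list was itself lower (median -0.16), and the cholesterol list lay below it by -0.36 (permutation p = 2.0e-05). Some dilution of resident cells is thus not excluded. More parenchyma in the day 2 dorsal SVZ pieces would lower radial glia genes most, and there the difference from the radial glia list was -0.72 (permutation p = 1.0e-05, the smallest the draws can give). These permutations take list members as independent, so their p measure the spread between genes and not between arrays. The cholesterol list was also picked for its fall, so the medians and not these p carry the comparison. A collection at another time of day stays open: clock genes as a set changed at day 2 (mixed set test with limma's fry, adjusted p = 0.00128 over 6 tests, 9 of 38 called lower), and the collection times are not given. That set test takes arrays of different regions as independent. Its p is too small if arrays of different regions share fish or a collection, which the labels do not say. In a second test, run after that one and after the values per array had been seen, a clock and glucocorticoid score of each array was added to the model, and the list stayed lower with a median of -0.66 (-0.53 without the score), which argues against that state as the whole cause as far as it also varied within groups; a biological effect of the lesion remains an untested candidate explanation.

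The fall of tiparp at day 2 was weighed in the same way. Of 75 radial glia and mature neuron genes 2, or 2.7%, fell as far as tiparp in the mean day 2 effect. This does not decide on dilution of resident cells, because tiparp was singled out for its fall. The cells that express it were not examined either. The clock set test (limma's fry, adjusted p = 0.00128) leaves the time of day open for tiparp as well, with the same limit on its p. With the score in the model the log2 change of tiparp was -0.64 (SE 0.165, adjusted p = 0.0447) in place of -0.88 (SE 0.155, adjusted p = 0.00118), so part of the fall went with the score and the call stayed by a thin margin. The score was low on the first day 7 array of each region too, where klf9 was at 4.768, 5.518 and 4.843 while the other day 7 arrays had 8.341 to 9.27, so this state may differ between fish or collections and not only with the lesion.

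The rise of subpallial and myelin genes in the day 7 parenchyma was weighed against the place of the dissection. If those pieces held more ventral tissue, other genes higher in unlesioned medial than dorsal SVZ tissue should rise too: 419 such genes outside the lists had a median of 0.26, above the highest of 1000 draws of matched genes (0.111). This result, of a test written before it was seen, is what more ventral tissue in these pieces would give. It cannot decide the question, because medial and dorsal SVZ tissue also differ in interneuron and myelin genes in general. A rise of such genes from another cause would raise the 419 genes too. The matched draws were of unrelated genes, so genes that move together can exceed them. At the preset correlation of 0.01 a single array did not carry the pattern, since the largest adjusted p of the subpallial list without 1 array was 0.000129, and that of the myelin list was 0.00224 (its median ran from 0.399 to 0.923), but with all arrays and an estimated correlation only the myelin list was called (adjusted p = 0.00364, subpallial 0.0856). The mean of the subpallial list also varied between parenchyma pieces at day 2 (4.858, 5.382 and 4.975). Day 2 replicate 2, at 5.382, was near day 7 replicates 1 and 2 (5.431 and 5.439). Day 7 replicate 3 was at 6.067, and the unlesioned arrays were at 4.789 and 4.848. Whether the lesion itself changed subpallial or myelin cells was not tested.

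Differences of the day 2 effect between the dorsal SVZ and the parenchyma were called for 10 genes, the named ones being ms4a17a.10 (-2.63), cst14b.1 (-2.58), arhgap27 (-2.44), tgm2l (-2.41), atf3 (-2.24), tubb5 (-1.97) and cyp51 (-1.76). Unlesioned means of tgm2l and atf3 lay under the table median, so these 2 differences are not exact. The count was 0 without parenchyma day 2 replicate 3, and each of the 7 calls ended without 2 or more of the arrays. Lists that differed at day 2 were microglia (median -1.33), lysosome (-0.46), cholesterol synthesis (-0.61) and erythrocytes (0.37), of which only cholesterol synthesis held with an estimated correlation (adjusted p = 0.0134; the others 0.0622, 0.162 and 0.368). Some cholesterol genes were low in unlesioned parenchyma (sqlea at 3.169) and had little room to fall there, so the size of that difference may depend in part on the level. The 14 members at least 1 above the table median there had a median difference of -0.55, all negative, and the other 8 had -0.69. These 2 sets were not compared by a test. At day 7 the lists of erythrocytes (0.35), cell cycle (0.23), mature neurons (-0.23), oligodendrocytes (-0.26), subpallial territory (-0.48) and cholesterol synthesis (-0.41) differed, and none held with an estimated correlation (adjusted p = 0.381, 0.563, 0.664, 0.117, 0.421 and 0.324). Between medial zone and dorsal SVZ the lists of cell cycle (0.29), neurogenic progenitors (0.10), mature neurons (-0.19) and cholesterol synthesis (0.33) differed at day 2, and pallial territory (-0.24) and cholesterol synthesis (0.44) at day 7, with adjusted p of 0.268, 0.176, 0.525, 0.162, 0.453 and 0.0923 with an estimated correlation. Several of these medians moved without 1 array. For dorsal SVZ against parenchyma at day 7, oligodendrocytes ran from -0.662 to -0.0857 and cholesterol synthesis reached -0.183. For medial zone against dorsal SVZ at day 2, mature neurons ran from -0.367 to -0.0244 and cholesterol synthesis reached 0.127. Pallial territory reached -0.0508 there at day 7.

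In the medial zone at day 2, the 1 group with 4 arrays, 8 of 125 named genes had 1 array far from the others, and chance gives about 1 in 20. Replicate 2 was low for tap2a (3.753; others 4.232 to 4.298) and jun (5.814; others 6.271 to 6.329) and high for cfap45 (4.949; others 3.945 to 4.080). Replicate 3 was low for tbr1b (6.109; others 7.354 to 7.594) and high for dlc (6.153; others 5.403 to 5.519) and cxcr5 (3.936; others 2.672 to 2.733). Replicate 4 was high for foxq1b (2.929; others 2.751 to 2.777) and nrgna (10.178; others 9.676 to 9.758).

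Probe sets without a single gene name, which the report does not use, also passed the test: 585 at day 2 and 76 at day 7 in parenchyma, 11 in dorsal SVZ and 14 in medial zone at day 2, of 54406.

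Other splits of the arrays were counted where each group had at least 3, and for the mean effects over regions, which include 2 groups of 2. With 10 splits no share under 0.05 can be reached: dorsal SVZ at day 2 gave 52 genes in the real split and at most 2 in another (1 split as large), dorsal SVZ at day 7 gave 0 and at most 11 (10 splits as large), day 7 against day 2 gave 221 and at most 17 in parenchyma (1) and 10 and at most 2 in dorsal SVZ (1). For day 7 against day 2 in the medial zone the real split gave 81 genes, the others at most 15, and 1 of 35 was as large. The mean day 2 effect over regions gave 751, at most 135 and 1 of 100, where arrays of different regions were taken as independent. These shares are the smallest that so many splits can give, and they were not adjusted for the number of split tests. No other split was as large in either, but chance is not excluded. Day 2 arrays of the same number had residual correlations of -0.061 to 0.239 across regions and those of different numbers -0.124 to 0.143, which overlap. A tie of day 2 arrays across regions is thus neither shown nor excluded. For the mean day 7 effect chance stays open. There 2 of 100 splits gave as many as the real 18, the other with 54, but the splits treat arrays of different regions as independent. Day 7 arrays of the same number had residual correlations of 0.077 to 0.224 across regions, against -0.197 to 0.025 for different numbers, and a random block left 12 of the 18 genes, or 9 with the day 7 arrays alone in blocks.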

How the results depend on the processing

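Some alternatives were chosen after the results had been seen: the fit without the 2 arrays of lowest quality weight, the random block at day 7 alone and the mean effects over regions. So were the split of the cholesterol list by level and the model with the clock and glucocorticoid score. The other alternatives were chosen before. Removal of the third of genes with the lowest mean and the replicate number as a random block (correlation 0.0214) kept all 15 counts within 1.5 times. The cause of the following moves was not tested, except that fits to fewer groups, and without 1 array, have fewer arrays, and that every probe set tests more features. Parenchyma arrays also varied most, with a median residual SD of 0.326 for genes above the table median (0.255 in dorsal SVZ, 0.285 in medial zone). The main model used a single variance per gene for all regions, which does not allow for this. Over every probe set the counts were 913 and 98 for parenchyma at days 2 and 7, 31 and 42 for dorsal SVZ and medial zone at day 2, 477, 4 and 30 for day 7 against day 2 in parenchyma, dorsal SVZ and medial zone, 2671 and 1315 between unlesioned regions, and 5 for the day 2 difference between dorsal SVZ and parenchyma. With only the groups of the region or comparison they were 80 and 2 for parenchyma at days 2 and 7, 1 for dorsal SVZ at day 7, 54 for medial zone at day 2, 59, 4 and 11 for day 7 against day 2, and 4 for that difference. With array weights they were 247 and 1 for parenchyma, 85 and 2 for dorsal SVZ at days 2 and 7, 124 for medial day 7 against day 2 and 6 for the difference. The trend and robust prior gave 2 for dorsal SVZ and 1 for medial zone at day 7, and 1 for the day 7 difference between dorsal SVZ and parenchyma. Quantile normalization again gave 38 for parenchyma and 1 for medial zone at day 7, 3 for the day 2 and 1 for the day 7 difference. Subtraction of the array median gave 2 for medial zone at day 7 and 1 for the day 7 difference. In parenchyma at day 2 it moved the median of all genes by -0.11 and gave 277 higher and 148 lower in place of 328 and 64. Without the 2 arrays of lowest weight the medial zone at day 7 had 1 and the day 2 difference 30.

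The replicate number was tried as a block. Day 7 arrays of the same number in different regions had residual correlations of 0.077 to 0.224. Those at day 2 had -0.061 to 0.239 and those without a lesion -0.154 to 0.002, so the numbers were not taken as pairs in the model. The medial zone had 4 day 2 arrays and the other regions 3, so equal numbers need not mean the same fish. The lowest klf9 at day 2 was on parenchyma replicate 3 (4.547), dorsal SVZ replicate 3 (4.767) and medial replicate 4 (4.434). A tie of day 2 arrays across regions is thus neither shown nor excluded. At day 7 alone all 9 pairs of the same number lay above all 18 of different numbers (-0.197 to 0.025), a hint from the data, not the design, that these arrays are tied across regions, which the model ignores. A random block of the day 7 arrays alone (correlation 0.113), chosen after the results had been seen, gave 24 for parenchyma at day 7, 222, 10 and 81 for day 7 against day 2, and 0 for the day 7 differences between regions. It gave 9 in place of 18 for the mean day 7 effect, and 271 in place of 344 for the mean difference of day 7 from day 2. With the replicate block the counts were 11 for parenchyma at day 7 (11 shared with the fit without it), 51 for medial zone at day 2 (47 shared), 5 and 21 for day 7 against day 2 in dorsal SVZ and medial zone (5 and 19 shared) and 2 for the day 2 difference between dorsal SVZ and parenchyma (2 shared).

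Leaving out 1 array gave counts of 231 to 433 and 16 to 98 for parenchyma at days 2 and 7, 14 to 42 and 0 to 4 for dorsal SVZ, and 24 to 105 and 0 to 10 for medial zone. Day 7 against day 2 ran from 135 to 286 in parenchyma, 4 to 6 in dorsal SVZ and 13 to 83 in medial zone, and the unlesioned regions from 798 to 1103 and 419 to 642. The differences of dorsal SVZ from parenchyma ran from 0 to 29 and 0 to 24 at days 2 and 7, and those of medial zone from dorsal SVZ from 0 to 10 and 0 to 6. Where this left 1 array in a group, that array was assumed to vary like the other groups. Of 271 called results of named genes 142, and of 97 called lists 42, were lost without at least 1 array. The median of 46 of these lists moved by over 1.5 times without at least 1 array. The sign turned for the subpallial list in the medial zone at day 7, which had a median of -0.0823 without unlesioned replicate 2 and 0.628 without unlesioned replicate 1. The signal over background of single probes could not be examined, as the scanner files were not available.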

Other observations

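The mean effects over the 3 regions and the model with a clock and glucocorticoid score were chosen after the results had been seen. In the mean day 2 effect 751 genes were called, 525 higher and 226 lower, and the 226 held genes of the circadian clock and targets of glucocorticoids. The clock list had 9 of 38 members lower and none higher, with a median log2 change of -0.41, and the glucocorticoid list 2 of 16 lower with a median of -0.43. The glucocorticoid-responsive factor klf9 changed by -2.35 (SE 0.632, adjusted p = 0.0346) and the clock repressor nr1d1 by -1.53 (SE 0.435, adjusted p = 0.0494). With the replicate number as a random block the call of nr1d1 ended (adjusted p = 0.0545) and that of klf9 stayed (adjusted p = 0.0366). That block used 1 correlation for all genes, 0.0214, and tied only arrays of the same number. At day 7 klf9 was low on replicate 1 of each region (4.768, 5.518 and 4.843) and high on the others (8.341 to 9.27), a closer tie. The block thus does not show that the call of klf9 holds if arrays share fish or a collection. Neither list had a called member in the mean day 7 effect, which called 18 genes.

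With the score in the model the mean day 2 count was 401, of which 346 were among the 751, and the counts were 320 in parenchyma (293 shared), 33 in dorsal SVZ (30 shared) and 41 in medial zone (38 shared) at day 2, in place of 392, 52 and 95. For day 7 against day 2 the score gave 180 in place of 221 in parenchyma (165 shared), 4 in place of 10 in dorsal SVZ (4 shared) and 15 in place of 81 in medial zone (14 shared), so most of the medial calls between the times did not hold with the score. A lost call alone does not show that the change went with the score, as a covariate can also raise the SE. The phagocyte gene mpeg1.1 had a mean day 2 change of 2.87 without and 2.98 with the score, and the microglia list a median of 1.58 and 1.64. The cell cycle list had a median of 0.59 without and 0.55 with it.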
